A study of Mus musculus with 26 samples.

How the data were processed

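Total RNA was extracted from mouse striatum and sequenced with a TruSeq preparation, per the labels' protocols. The 26 libraries fall into 9 groups by their labels: 3 libraries per group for R6/1, CHL2 and their wild types, 2 for each control-AAV group and 4 for Elk-1-AAV R6/1. The tables have no header; each row names its groups, and those names give the control vector as mCherry, which the labels call control AAV. The submitters' processing notes name TopHat, Bowtie, Cufflinks, Cuffdiff and the mm9 genome, with no versions. The strandedness of the counting and the gene annotation are not given in the sources used here.

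The authors deposited 5 tables, 1 per comparison, of 14539, 14320, 14402, 12980 and 12701 genes. Each holds the group FPKM values made by the authors' pipeline, 1 pooled value per group and gene, and no column per library. Each also holds the authors' deposited log2 fold change of these FPKM values, given as infinite where 1 group is at 0, a test statistic (a score of the authors' program) and the deposited p-value and q-value. The deposited p-values come in steps of 5e-05, which is also their lowest value, and the q-values equal the Benjamini-Hochberg adjustment of the p-values over the table's rows. For 5, 3, 3, 4 and 0 rows the deposited log2 fold change differed from the ratio of the group values by more than 0.01. Between 11.5% and 13.3% of rows share their listed position with another gene, so values of such genes may hold the same reads. Reads shared between paralogs, such as the histones, ribosomal proteins and globins, are uncertain for the same reason. Rows named for microRNAs and small nucleolar RNAs, which hold between 6.90% and 28.1% of the summed FPKM of a group, were left out of all list and correlation computations. Positions are given as listed, on mm9; whether starts count from 0 or 1 is not stated. The 4-week, 8-week and 1-year tables have no Xist row, and no Hox or mitochondrially encoded gene is listed in any table, so those 2 lists gave no result.

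Depth per library and read counts are unknown, since the values are pooled, and no interval, SD or test of library spread could be computed. The planned limma fits on log2(FPKM + 1), the set tests and the fits with a replicate block need a value per library and were not run. As fixed for that case before the data were examined, calls are the authors' deposited q below 0.05, reported as theirs. Whether the libraries of a group come from separate animals is not stated, so these p-values measure only the spread between these libraries, which may be technical.

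From the group values, log2(FPKM + 1) changes were computed for genes with a mean FPKM of at least 0.5 over both groups; the added 1 understates the change of low genes. The 28 gene lists (projection neuron, pathway, glial, immune, vascular, neighbouring-tissue and gene-family lists) were fixed before the data were examined. A list's median change was placed by percentile among 10000 random lists matched on mean expression in 25 bins, and percentiles below 2.5 or above 97.5 are called outside. Of 130 list results, 87 lay outside. Random lists draw genes independently, while genes of a cell type can move together, so a percentile describes these pools only. Bootstrap 95% intervals of a list median came from 2000 draws of the list's genes within the pooled values. They hold no spread between libraries or animals. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the deposited p-values of that list. Overlaps of called genes were tested with one-sided Fisher's exact tests, adjusted over 64 tests. Transcript length is the longest transcript of a symbol in the GENCODE M21 annotation, used for lengths only and matched for at least 98.9% of genes.

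The difference of 2 deposited log2 fold changes was tested with standard errors implied by each deposited p-value under a normal test, an alternative chosen after seeing the data. For a gene at the lowest p-value the implied error is an upper limit and grows with its effect, so a difference that did not pass says nothing about such a gene, and counts of differences can be too low. For the 8-week against 4-week difference it was tested on simulated data over 13972 genes with 200 changed. It recovered 0% of differences of 0.5 log2 units, 38.5% of 1 and 90% of 2, with 0, 2 and 3 false calls. The simulated effects and p-values were drawn from the same implied errors and normal test, so few false calls were built in. Its error rate with p-values of the authors' own test is unknown. The random-list percentile was tested on the permuted 8-week table of 14105 genes: lists of 40 genes lay outside in 6% of 200 draws with no shift and in 99% with a shift of 0.15. For the shared control-AAV R6/1 pool, 100 simulations drew unchanged groups of 2, 2 and 4 libraries with the variances implied by the deposited p-values of the 10-week genotype table.

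Genes were named by a rule fixed before the data were examined. Elk1, Htt, Drd1a, Drd2, Penk, Pde10a, Ppp1r1b, Adora2a, Fos, Egr1, Arc and Gfap are named in every comparison. To these come the 8 largest rises and 8 largest falls among called genes with an FPKM of at least 1 in 1 group, without unnamed loci and small RNAs. The 3 members of smallest p of each list outside the random range are added, ties broken by the size of the change. The part of the rule on libraries that do not overlap could not be applied. It gave between 60 and 92 genes per comparison, and from the lists the text takes mainly those with a called gene; some genes it names are not reported here. Ttr, Pmch, Oxt, Avp, Trh, Prl, Gh, Igj, Cxcl13, B2m, Cd74, Grin2a, Grin2b, Srf, Hbb-b1, Prkcd, Slc17a6, Egr2, Npas4, Junb, Kl, Elk3, Elk4, Cd4, Hspa1b, Ccl5, Rps14 and the sex-linked genes are also given where the rule does not name them, as are genes listed for overlaps and differences and as the called members of a list; these were chosen after their values were seen. Alternatives were a pseudocount of 0.1, other filters on mean FPKM, median-shifted and quantile normalized values, stricter and looser thresholds and, added later, matching on transcript length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.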

Results

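RNA sequencing of mouse striatum was used to compare Huntington's disease models with wild-type mice and to ask what an adeno-associated virus (AAV) carrying Elk-1 does in one of them. R6/1 mice carry a transgene with exon 1 of the human huntingtin gene, and the CHL2 line is the other model named in the labels. Elk-1 is a transcription factor of the ETS family that acts with SRF on activity-induced genes. The 26 libraries form 9 groups: R6/1 and wild type at 4 weeks and at 8 weeks, and CHL2 and wild type at 1 year, with 3 libraries each. The remaining groups were injected and sampled at 10 weeks: control-AAV wild type and control-AAV R6/1 with 2 libraries each, and Elk-1-AAV R6/1 with 4. The authors' deposited tables give 1 FPKM value per group and gene and their own test, with no value per library, so the spread between libraries and the depth of each library are unknown here. A gene is said to have risen or fallen where its q in the authors' deposited table was below 0.05. In the accounts of the single comparisons, a called gene given with a value and no q had the lowest q its table holds: 0.0145 at 4 weeks, 0.00160 at 8 weeks, 0.00303 in CHL2, 0.00312 between the control-AAV groups and 0.0122 under Elk-1 AAV in the authors' deposited tables.

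In R6/1 striatum at 4 weeks few genes differed from wild type. The authors' deposited table called 68 of 14539 genes, 40 higher and 28 lower. Among those lower were markers of striatopallidal neurons and of neuronal activity: Penk, the precursor of enkephalin, went from an FPKM of 761 to 524 (log2 fold change -0.54, q = 0.0428 in the authors' deposited table). Adora2a, an adenosine receptor gene, fell from 119 to 85.9, and Egr2, an immediate-early transcription factor, from 6.36 to 3.83 in the authors' deposited table. Those higher included the NMDA receptor subunits Grin2a (2.99 to 4.80) and Grin2b (7.18 to 11.3) in the authors' deposited table. Elk1 on the X chromosome (mm9 20510520 to 20527726) stood at 20.3 and 21.2, and Htt on chromosome 5 (35104388 to 35255170) at 18.1 and 19.7, with neither called in the authors' deposited table.

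The largest rises at 4 weeks in the authors' deposited table were the potassium channel Kcnh7 (log2 fold change 0.84), the cell adhesion gene Pcdh11x (0.76), Fign (0.74), Tcp11l1 (0.73), the neuregulin receptor Erbb4 (0.69), Grin2a (0.68), the serotonin receptor Htr2a (0.68) and Odz1 (0.68). Its largest falls were Oxt, the precursor of oxytocin (68.8 to 18.9, log2 fold change -1.86), Cldn26 (-1.25, q = 0.0428), Prdm12 (-1.19), Gpx6 (-1.10), Aldh3b2 (1.55 to 0.771, q = 0.0428), Prkcd (-0.96), Trh (-0.94) and Zic4 (-0.77) in the authors' deposited table. Of 40 genes shared by all striatal spiny projection neurons, 36 had lower values in R6/1, but only Lrrc10b was called (log2 fold change -0.40, q = 0.0428 in the authors' deposited table). Their median log2(FPKM + 1) change was -0.20, at percentile 0 among 10000 random lists of matched expression. In the indirect pathway list, Penk and Adora2a were called and 8 of 10 were not (median -0.20, percentile 0), while 0 of 11 direct pathway genes were called (median -0.042, percentile 18.37). Activity-induced genes had a median of -0.18 (percentile 0), with Egr2 and Arc called of 38, and 13 lower adjusted over the list alone. Arc went from 75.0 to 54.6 (q = 0.0428), while Egr1 (129 to 101, q = 0.249), Fos (16.3 to 13.8, q = 0.939) and Npas4 (12.1 to 9.02, q = 0.154) did not pass in the authors' deposited table. Drd1a (59.2 and 52.9), Drd2 (83.3 and 68.6), Pde10a (152 and 131), Ppp1r1b (848 and 656) and the astrocyte gene Gfap (64.9 and 69.0) were not called in the authors' deposited table (q from 0.497 to 0.999).

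Among 42 neurotransmitter receptors, 3 rose at 4 weeks and 10 did adjusted over the list alone (median 0.074, percentile 100). The rises sat in genes with long transcripts: the longest annotated transcript had a median of 9029 bases for the genes called higher, 2526 for those called lower and 3424 for all genes. Across the genes compared, the change correlated with transcript length (Spearman 0.48, across genes, which are not independent replicates). The 13 tested septal, hypothalamic and olfactory tubercle genes had a median of -0.32 (percentile 0), with Oxt, Trh and Zic2 called lower in the authors' deposited table. Prkcd and 2 other genes of the thalamus and pallidum list also fell, although that list's median was 0.053 (percentile 87.87); it turned to -0.097 (percentile 0.55) with genes of a mean FPKM of at least 2. Cytosolic ribosomal protein genes (-0.12) and nuclear oxidative phosphorylation genes (-0.092) lay at percentile 0 with 0 genes called, and the latter list lay at percentile 39.08 among random lists matched on transcript length too.

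At 8 weeks the striatum of R6/1 mice showed a broad fall of the genes that define its projection neurons. The authors' deposited table called 877 of 14320 genes, 764 lower and 113 higher. All 40 shared spiny projection neuron genes fell, with a median log2(FPKM + 1) change of -0.95 (percentile 0). The sodium channel subunit Scn4b went from 350 to 80.4 (log2 fold change -2.12), the phosphodiesterase Pde10a from 209 to 70.2 (-1.58), and DARPP-32, encoded by Ppp1r1b, from 979 to 399 (-1.30) in the authors' deposited table. Both dopamine receptors fell, Drd1a from 68.4 to 29.5 and Drd2 from 104 to 42.3, as did Penk from 803 to 222 and Adora2a from 128 to 43.3 in the authors' deposited table.

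Of the direct pathway list 5 of 11 fell, including Chrm4 (log2 fold change -1.17) and the dynorphin precursor Pdyn (-0.89) in the authors' deposited table, and of the indirect pathway list 5 of 10. The list medians were -0.16 (percentile 1.39) and -1.04 (percentile 0). Activity-induced genes fell in 24 of 38 cases (median -0.60, percentile 0; 31 adjusted over the list alone). Egr2 went from 8.92 to 1.01 (log2 fold change -3.15), Egr3 from 51.5 to 21.8, Egr1 from 151 to 70.6, Arc from 63.8 to 27.0 and Fos from 20.2 to 13.6 (q = 0.00900) in the authors' deposited table. Srf itself fell from 21.3 to 15.1 (q = 0.00556) in the authors' deposited table. Elk1 stood at 23.4 and 20.0 (q = 0.428), Elk4 at 6.04 and 5.30 and Htt at 21.7 and 21.4 in the authors' deposited table, with none of these 3 called. Among neurotransmitter receptors 18 of 42 fell, with the cannabinoid receptor Cnr1 (log2 fold change -1.33) and Gabrd (-1.12) among them in the authors' deposited table. Of the potassium and calcium channels 12 of 38 fell, including Kcnh4 (-1.71), Kcnab1 (-1.06) and Kcnip2 (-0.95) in the authors' deposited table.

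The largest falls at 8 weeks in the authors' deposited table were Gpx6 (3.14 to 0.199, log2 fold change -3.98), Egr2, Fgf3 (-2.53), Dmkn (-2.33), the ryanodine receptor Ryr1 (-2.30), the phosphatase Ptpn7 (-2.17), Clspn (-2.15) and Scn4b. The largest rises were Rgs13 (1.78, q = 0.0399), Aldh1a2 (1.33, q = 0.0101), the vasopressin precursor Avp (1.22, q = 0.0315), Fmod (1.18, q = 0.00300), Sfmbt2 (1.17), Gli1 (1.07, q = 0.0359), Ifit1 (1.06, q = 0.0366) and the smooth muscle actin Acta2 (1.06) in the authors' deposited table. Interferon and antigen presentation genes were higher as a list (median 0.25, percentile 100): 3 of 32 rose, with Ifit1 and H2-D1 (16.4 to 25.6) among them in the authors' deposited table, and 29 were not called. Choroid plexus and ependymal markers fell in 9 of 18 cases (median -1.01, percentile 0), including Slc4a5 (log2 fold change -1.56), Cldn2 (-1.52) and Aqp1 (-1.47) in the authors' deposited table. Markers of cortical excitatory neurons fell in 8 of 15 cases (median -0.50, percentile 0), with Neurod6 (-0.92) and Tbr1 (-0.67) among them in the authors' deposited table. Choroid plexus and cortical markers stand for neighbouring tissue, and a different share of it between the 8-week pools was not tested. In the interneuron list Vip (-1.22) and Npy (-0.68) fell and Calb2 rose from 15.1 to 26.4 in the authors' deposited table. The oligodendrocyte genes Ugt8a (-0.46, q = 0.0111), Fa2h (-0.41, q = 0.0315) and Gsn (-0.40, q = 0.0385) and the cholesterol synthesis gene Sc4mol (-0.50) fell in the authors' deposited table. Gfap (56.9 and 49.2, q = 0.528) was not called in the authors' deposited table. Of 18 astrocyte and 20 microglial genes 0 were called, and the list medians were -0.060 and -0.035.

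In CHL2 striatum at 1 year the genes of projection neurons were again lower than in wild type, and hypothalamic markers were higher. The authors' deposited table called 525 of 14402 genes, 284 lower and 241 higher. Of the 40 shared spiny projection neuron genes, 28 fell and the other 12 had lower values without passing (median -0.54, percentile 0; 36 adjusted over the list alone). Penk went from 887 to 378 (log2 fold change -1.23), Scn4b from 265 to 112 (-1.25), and Adora2a from 106 to 50.5 (-1.07) in the authors' deposited table. Ppp1r1b went from 885 to 458 (-0.95), Pde10a from 148 to 85.7 (-0.78), Drd1a from 61.2 to 37.7 (-0.70) and Drd2 from 82.5 to 50.5 (-0.71) in the authors' deposited table. Elk1 (20.4 and 20.7, q = 0.987), Htt (18.4 and 18.8, q = 0.973) and Gfap (82.2 and 88.5, q = 0.816) were not called in the authors' deposited table.

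Of the direct pathway list 6 of 11 fell (median -0.38, percentile 0), including Tac1, the substance P precursor (log2 fold change -0.50) in the authors' deposited table. Of the indirect list 5 of 10 fell (median -0.64, percentile 0), including Upb1 (-1.30) in the authors' deposited table. Of the 38 activity-induced genes 9 fell and 1 rose (median -0.18, percentile 0). Npas4 (-0.82), Junb (-0.49), Egr2 (-0.69, q = 0.00750) and Arc (-0.42, q = 0.0163) were among those lower and Nr4a3 rose from 4.56 to 7.38 in the authors' deposited table. Egr1 (99.3 and 79.8, q = 0.110) and Fos (20.8 and 18.2, q = 0.589) did not pass in the authors' deposited table. Oligodendrocyte genes fell in 7 of 21 cases (median -0.31, percentile 0), with Aspa (-0.86), Cldn11 (-0.72) and Mal (-0.69) lowest in p in the authors' deposited table.

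The largest rises in CHL2 in the authors' deposited table were Pmch, the precursor of melanin-concentrating hormone (3.07 to 53.2, log2 fold change 4.12), Krt2 (1.81), Vgll3 (1.78), Fezf1 (1.76), the matrix proteoglycan gene Dcn (1.65), Otp (1.56, q = 0.0366), Trhr (1.46) and Trh (1.46). Septal and hypothalamic genes rose in 8 of 15 cases (median 0.58, percentile 100), including Gal (1.27) and Oxt (15.3 to 35.0) in the authors' deposited table. This list went the other way in R6/1 at 4 weeks (median -0.32). Whether the CHL2 and wild-type pools held different shares of neighbouring tissue was not tested. The largest falls were the growth hormone gene Gh, listed at 1.18 in wild type and at 0 in CHL2, Mafa (-2.28), Gpx6 (-2.21), Slc4a11 (-1.81), Tmem52 (-1.81, q = 0.0366), Col6a4 (-1.42), Fam83d (-1.36) and Ptprv (-1.32) in the authors' deposited table. The blood genes Hbb-b1 (36.5 to 16.3) and Alas2 (3.35 to 1.41) fell in the authors' deposited table (list median -0.85, percentile 0); Hbb-b1 shares its listed position with another gene. Receptor genes went both ways, 6 higher and 4 lower of 42: Gabra2 rose from 17.1 to 39.4 and Grin2b from 7.46 to 10.6, and Gabrd fell from 64.6 to 36.7 in the authors' deposited table. Microglial genes had lower values in 20 of 20 cases with 0 called (median -0.22, percentile 0), and C1qb stood at 77.6 and 62.6 (q = 0.155) in the authors' deposited table. The heat shock gene Hspa1b rose from 2.06 to 3.68 (q = 0.0128) in the authors' deposited table. As at 4 weeks, the change correlated with transcript length (Spearman 0.40 across genes), and ribosomal protein (-0.22) and oxidative phosphorylation genes (-0.21) lay at percentile 0 with 3 called lower in each list.

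**Figure D1:**
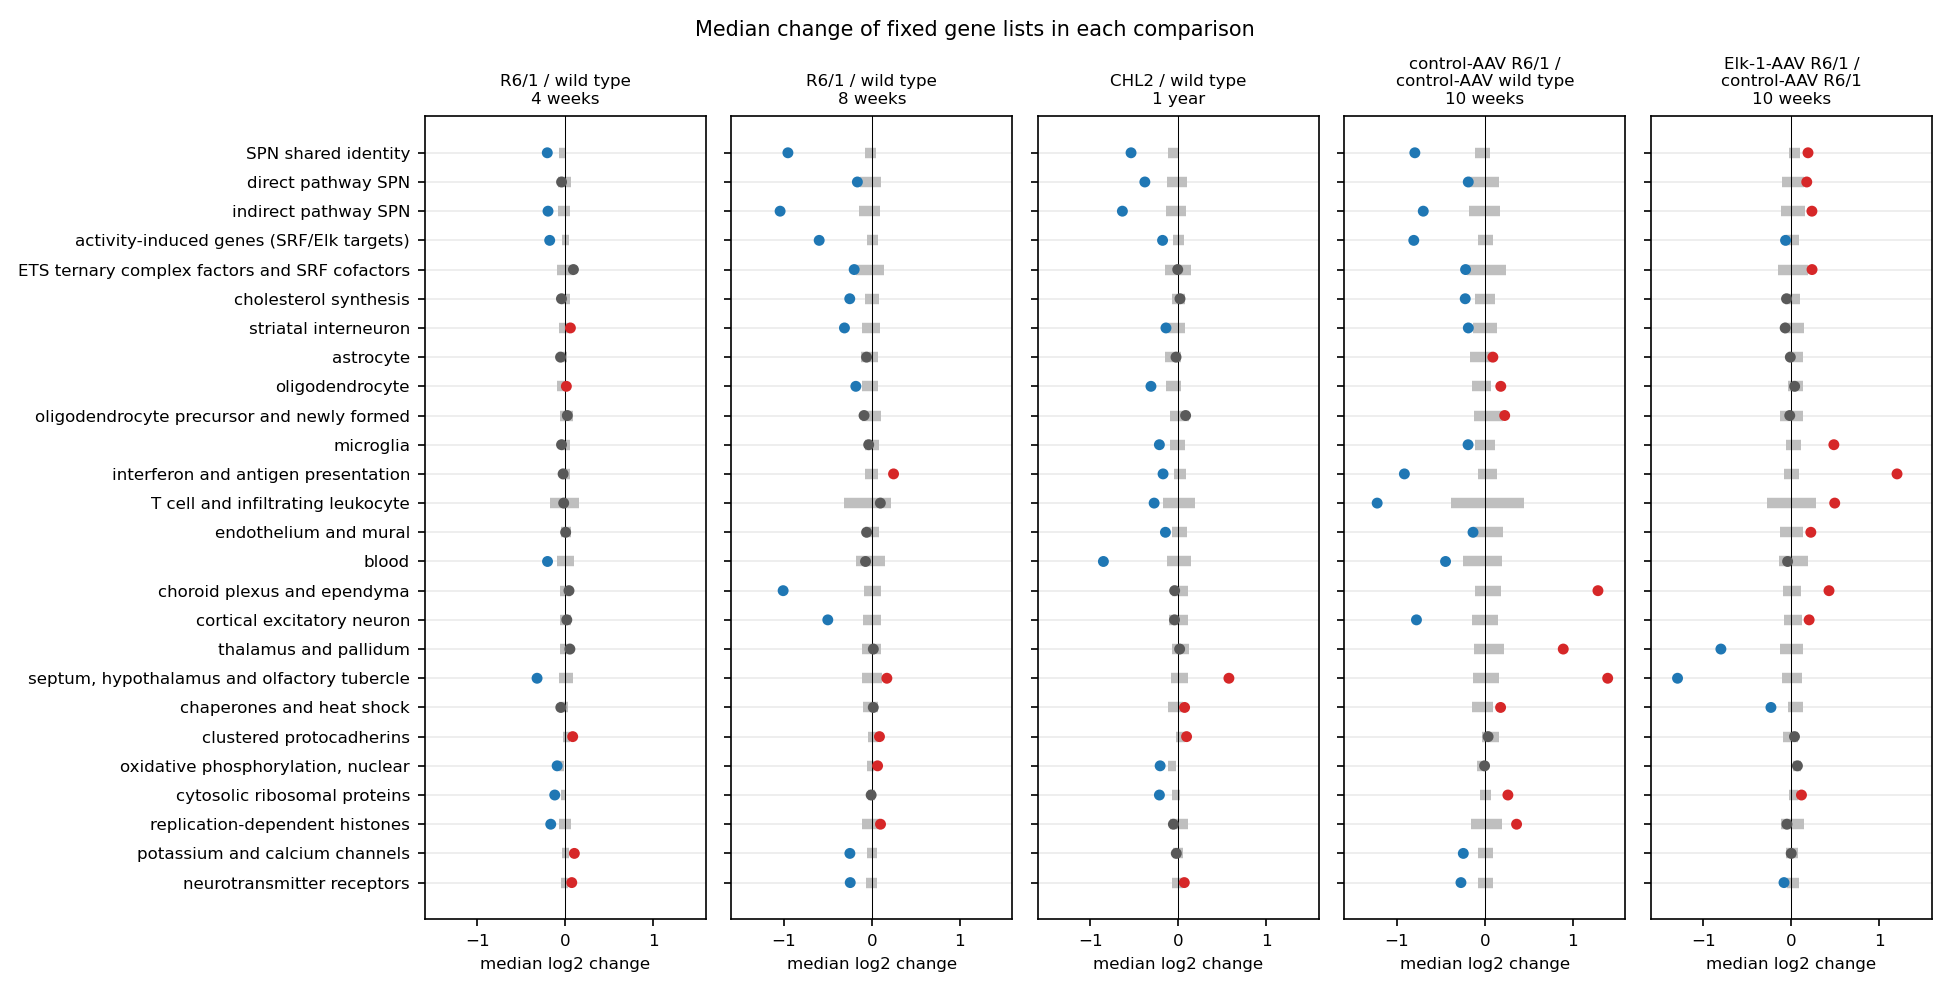
Median log2(FPKM + 1) change of each fixed gene list (rows; SPN, spiny projection neuron) in the 5 comparisons (panels), with the horizontal axis in log2 units. Grey bars span the central 95% of 10000 random lists of matched expression, and red or blue points lie above or below it; the shared spiny projection neuron list sits at -0.20, -0.95, -0.54, -0.80 and 0.19 from left to right.

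The overlap of called genes between the genotype tables depended on the pair of tables and on the direction. Of 758 genes lower in R6/1 at 8 weeks and listed in both tables, 192 were also lower in CHL2, against 15.1 expected for independent lists (Fisher's exact test, odds ratio 50.2, adjusted p = 8.45e-181). In the other direction, 27 of 112 were shared against 1.87 expected (adjusted p = 1.44e-23), among them Calb2, the vesicular glutamate transporter Slc17a6, Scn9a, Fmod and Pcdh8. Genes lower at 4 weeks were lower at 8 weeks in 10 of 25 cases against 1.34 expected (adjusted p = 6.04e-07): Adora2a, Arc, Clspn, Egr2, Gpx6, Krt9, Lrrc10b, Peg10, Penk and Plk5. Of the 40 genes higher at 4 weeks 1 was higher at 8 weeks, Gpr149, against 0.316 expected (adjusted p = 0.396), and 14 were higher in CHL2 against 0.664 (adjusted p = 3.09e-15). The 4-week and CHL2 tables share the correlation of change with transcript length (Spearman 0.48 and 0.40, against -0.11 at 8 weeks), and the genes called higher in CHL2 have a median transcript length of 5193 bases. Of 27 genes lower at 4 weeks, 9 were lower in CHL2 against 0.532 expected (adjusted p = 2.98e-09), and 10 were higher there against 0.448 (adjusted p = 1.98e-11), Oxt, Trh, Zic1 and Zic2 among them. Genes higher at 4 weeks were lower at 8 weeks in 5 of 40 cases against 2.14 expected (adjusted p = 0.102), which did not pass: Cntnap5b, Grin2a, Grin2b, Htr2a and Kcnq3. Grin2b was thus called higher at 4 weeks and lower at 8 weeks (log2 fold change 0.66 and -0.49 in the authors' deposited tables). It was also higher in CHL2 (0.50), which shares the length trend with the 4-week comparison. How much of this change of sign comes from that trend was not tested. Across 14004 genes the changes at 8 weeks and in CHL2 correlated with Pearson r 0.45 and Spearman rho 0.34, those at 8 and at 4 weeks with 0.19 and 0.14. Those at 4 weeks and in CHL2, which share the length trend, correlated with 0.32 and 0.41 across 14041 genes. The p-values of these tests treat genes as independent, which they are not.

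Set side by side, the effects at 8 and at 4 weeks were -1.58 and -0.21 for Pde10a, -1.21 and -0.16 for Drd1a and -1.85 and -0.54 for Penk in the authors' deposited tables. A test of the difference, built after the tables were seen from errors implied by the deposited p-values, gave 187 of 13972 genes, 158 more negative at 8 weeks and 29 more positive. Where a deposited p-value is at its lowest value, 5e-05, as at 8 weeks for Penk, Pde10a and Drd1a, the implied error is an upper limit, so the test does not decide whether the effects of these 3 genes differed between the ages. The choroid plexus genes Folr1 (adjusted p = 0.00387) and Kl (0.00160) passed towards lower values at 8 weeks, and Otp (0.0178) and Oxt (0.00926) towards higher values. Between CHL2 and R6/1 at 8 weeks 85 of 14003 genes differed, 77 of them more positive in CHL2, among them Nr4a3 (adjusted p = 9.43e-05), Nov (9.43e-05), Trh (0.0172) and Cldn2 (0.0348). Those more negative in CHL2 numbered 8, with Ifit1 (0.0353), Ndn (0.000303) and H2-D1 (0.0222) among them. Change correlated with transcript length at 0.48 at 4 weeks and 0.40 in CHL2, but at -0.11 at 8 weeks (Spearman). Both difference tests set the 8-week effects against effects with that trend, and how far it tilts their counts was not tested.

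**Figure D2:**
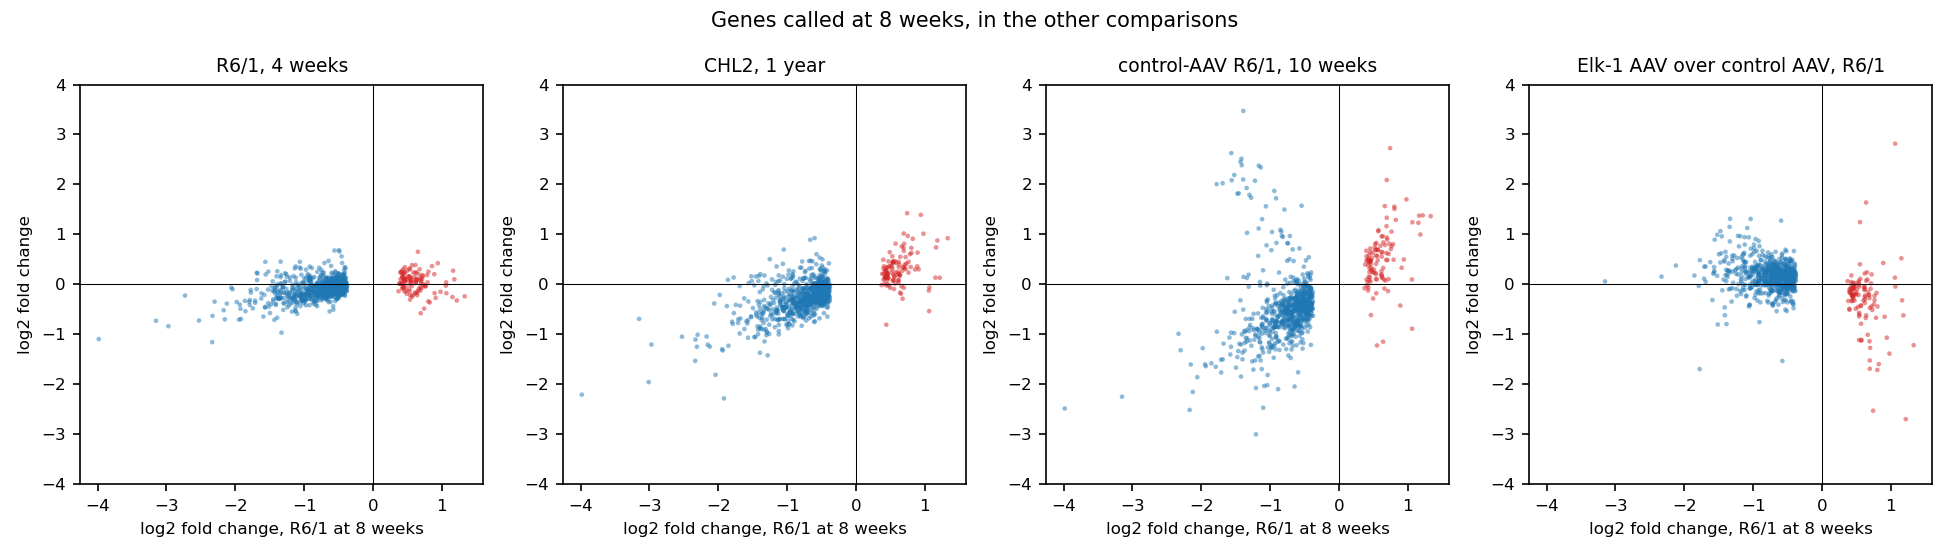
Log2 fold changes of the genes called at 8 weeks (points; blue lower, red higher in R6/1) from the authors' deposited tables, with the 8-week value on the horizontal axis and the value in 1 other comparison on each vertical axis, both in log2 units. The 8-week lowered genes have median log2(FPKM + 1) changes of -0.088 at 4 weeks, -0.24 in CHL2, -0.47 in control-AAV R6/1 mice and 0.15 under Elk-1 AAV.

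In control-AAV mice at 10 weeks the R6/1 pool again had low projection neuron and activity-induced genes, and it also had low interferon genes and high markers of neighbouring brain tissue. The authors' deposited table called 420 of 12980 genes, 326 lower and 94 higher. Shared spiny projection neuron genes fell in 26 of 40 cases (median -0.80, percentile 0): Scn4b from 172 to 38.6, Ppp1r1b from 816 to 374, Pde10a from 54.8 to 20.7 and Lrrc10b from 88.6 to 32.3 in the authors' deposited table. Oligodendrocyte genes had higher values in 19 of 21 cases with 0 called (median 0.18, percentile 100). Of 18 astrocyte genes Fabp7 rose (54.6 to 109 in the authors' deposited table), and the list median was 0.091 (percentile 98.66, or 95.64 with quantile normalized values, inside the random range). Penk went from 749 to 250, Adora2a from 94.2 to 39.6, Drd1a from 39.1 to 19.5 and Drd2 from 59.3 to 36.7 (q = 0.0389) in the authors' deposited table. Of the 38 activity-induced genes 20 fell (median -0.81, percentile 0), including Klf2 (log2 fold change -2.50), Cyr61 (-2.28), Egr2 (-2.25), Arc (118 to 36.1), Egr1 (173 to 66.9) and Fos (34.9 to 17.1) in the authors' deposited table. Elk1 (17.0 and 14.8, q = 0.926), Htt (11.1 and 11.3, q = 0.998), Srf (21.4 and 16.8, q = 0.624) and Gfap (log2 fold change 0.30, q = 0.681) were not called in the authors' deposited table.

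All 30 measured interferon and antigen presentation genes had lower values in the control-AAV R6/1 pool and 13 fell (median -0.92, percentile 0). Cd74, the invariant chain of MHC class II, went from 103 to 18.2, H2-Ab1 from 45.5 to 7.70, and Gbp2 from 9.40 to 2.12 in the authors' deposited table. B2m went from 224 to 129 in the authors' deposited table. Markers of other tissues rose: Ttr, the main transcript of choroid plexus, from 333 to 1547, and Kl from 2.36 to 6.95 in the authors' deposited table. Prkcd went from 7.11 to 21.4, Slc17a6 from 7.73 to 19.5, Calb2 from 25.7 to 75.3, Trh from 5.78 to 22.0 and Zic2 from 2.40 to 8.76 in the authors' deposited table. By list, 9 of 18 choroid plexus genes (median 1.29), 8 of 14 thalamus and pallidum genes (0.89) and 5 of 14 septal and hypothalamic genes (1.40) rose, all at percentile 100. Meanwhile 8 of 15 cortical excitatory neuron genes fell (-0.78, percentile 0). The largest rises in the authors' deposited table were Morn3 (listed at 0 in wild type and 1.78 in R6/1), Pmch (log2 fold change 6.44, q = 0.0203), Oxt (2.81), Irs4 (2.72), Lhx9 (2.52, q = 0.0357), Kcne2 (2.45, q = 0.00983), Col8a2 (2.38) and Calcr (2.27, q = 0.0251). Its largest falls included Gbp8, Cstl1 (2.02 in wild type), Plaur (1.71), Kdm5d (1.70), Cxcl13 (1.68) and Uty (1.12), all listed at 0 in R6/1. Iigp1 (log2 fold change -3.70) and Gbp5 (-3.30, q = 0.0404) followed in the authors' deposited table.

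Kdm5d and Uty lie on the Y chromosome, and the AAV pools differed in sex-linked transcripts. The Y-linked gene Eif2s3y stood at 12.6 in control-AAV wild type, 0.0289 in control-AAV R6/1 and 6.12 in Elk-1-AAV R6/1, and the X-inactivation transcript Xist at 12.8, 29.0 and 19.8 in the authors' deposited tables. In the uninjected groups Eif2s3y lay between 21.5 and 28.8 in the authors' deposited tables. Both AAV comparisons thus differ in sex-linked transcripts as well as in genotype or vector. The labels give no sex, and an effect of sex on the calls of these comparisons could not be separated. Of the genes lower at 8 weeks, 219 of 712 were also lower at 10 weeks against 17.8 expected (adjusted p = 2.07e-205). Another 15 were higher against 5.08 expected (adjusted p = 0.000277), among them the choroid plexus genes Folr1, Kcne2, Clic6, Kl and Sostdc1. Of the genes lower at 4 weeks, 11 of 24 were higher at 10 weeks against 0.171 expected (adjusted p = 8.39e-18): Baiap3, Gpx3, Magel2, Ngb, Oxt, Peg10, Prkcd, Trh, Zic1, Zic2 and Zic4.

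Under Elk-1 AAV, R6/1 striatum had more Elk1 and more interferon and antigen presentation transcripts than the control-AAV R6/1 pool, and less of the hypothalamic and thalamic transcripts. Elk1 went from 15.1 to 30.1 (log2 fold change 1.00, q = 0.0122) in the authors' deposited table, where 73 of 12701 genes were called, 38 higher and 35 lower. All 33 measured interferon and antigen presentation genes had higher values and 17 rose (median 1.20, percentile 100; 32 adjusted over the list alone). The largest rises in the authors' deposited table were the chemokine Cxcl13 (listed at 0 and 3.41), the immunoglobulin joining chain Igj (2.91 to 39.1), Irf7 (1.48 to 10.8), Ifit1 (1.13 to 7.92), Ifi27l2a (7.16 to 49.1), Iigp1 (0.579 to 3.43, q = 0.0215), Oasl2 (1.69 to 9.46) and Isg15 (4.59 to 22.6). As for antigen presentation, B2m went from 132 to 305 and Cd74 from 18.7 to 41.9 in the authors' deposited table. Of 20 microglial genes 4 rose (median 0.48, percentile 100), including C1qa (72.1 to 131), C1qb (59.7 to 103) and Ctss (74.5 to 123) in the authors' deposited table.

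Shared spiny projection neuron genes had higher values under Elk-1 AAV in 34 of 39 cases, with a median change of 0.19 (percentile 100), and 0 of them were called. Cortical excitatory neuron genes also had higher values, in 11 of 15 cases (median 0.20, percentile 99.97), with 0 called. Drd1a stood at 19.9 and 22.8, Drd2 at 37.6 and 44.8, Penk at 256 and 289, and Pde10a at 21.2 and 24.5 in the authors' deposited table. Adora2a stood at 40.5 and 47.8, Ppp1r1b at 383 and 527 (q = 0.729) and Kcnj4 at 56.3 and 83.5 (q = 0.0960) in the authors' deposited table. Over all genes, 624 had an unadjusted p below 0.05, against 635 expected by chance. The direct and indirect pathway lists had medians of 0.17 (percentile 99.11) and 0.23 (percentile 99.92), with 0 genes called. The activity-induced genes had a median of -0.066 (percentile 1.98, or 2.66 with a pseudocount of 0.1, inside the random range) and 0 of 37 were called. Fos stood at 17.5 and 16.5, Egr1 at 68.5 and 78.9 and Arc at 36.9 and 45.6 in the authors' deposited table. The others included Egr2 at 1.56 and 1.62 and Junb at 35.1 and 55.9 (q = 0.0635) in the authors' deposited table. Htt (11.6 and 11.7), Gfap (101 and 129), Srf (17.2 and 20.7), Elk3 (1.77 and 2.29) and Elk4 (2.32 and 2.08) were not called in the authors' deposited table.

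The largest falls under Elk-1 AAV in the authors' deposited table were Oxt (112 to 9.04, log2 fold change -3.64, q = 0.0215), Avp (-2.70, q = 0.0215), Irs4 (-2.53), Trh (-2.42), Calcr (-2.02, q = 0.0435), the synaptic organiser Cbln1 (-1.82), Calb2 (-1.72) and Slc17a6 (-1.69). By list, 4 of 14 thalamus and pallidum genes (median -0.80) and 3 of 14 septal and hypothalamic genes (-1.30) fell, both at percentile 0, and Prkcd went from 21.9 to 7.16 in the authors' deposited table. Choroid plexus genes had a median of 0.43 (percentile 100) with Kl called higher (7.12 to 13.7), and Ttr stood at 1585 and 2236 without being called in the authors' deposited table. The authors' deposited table also listed the pituitary hormone genes Prl (34.3 to 156) and Gh (22.4 to 92.3) as higher, both named here after their values were seen.

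The genes lowered in R6/1 at 8 weeks, taken from other animals, had a median change of 0.15 under Elk-1 AAV over 687 genes, with 527 above 0 (percentile 100; random lists 0.00 to 0.03). Those raised at 8 weeks had a median of -0.20 over 108 genes, with 87 below 0 (percentile 0). Few passed the authors' threshold. Of the lowered genes Dbp, Kl and Stac2 rose and Peg10 fell. Of the raised genes 12 fell, including Avp, Calb2, Slc17a6, Magel2 and Agt, and 3 rose, with H2-D1 and Ifit1 among them. Avp, Calb2, Slc17a6, Magel2 and Agt were each also called higher in the control-AAV R6/1 pool than in control-AAV wild type. Kl was called higher there too, so its rise under Elk-1 AAV moved it further from control-AAV wild type. Adding the 2 steps, Elk-1-AAV R6/1 over control-AAV wild type, the 8-week lowered genes had a median of -0.35 against -0.46 for the control-AAV R6/1 pool, and the shared spiny projection neuron genes -0.59 against -0.81. Of the 35 genes lower under Elk-1 AAV, 31 were higher in the control-AAV R6/1 pool than in control-AAV wild type against 0.261 expected for independent lists, and 16 of 38 higher under Elk-1 AAV were lower there against 0.952. Both comparisons use the same control-AAV R6/1 libraries, in opposite directions. Their log2 fold changes correlated at -0.56 across 12574 genes, against -0.58 in simulations with no effect (range -0.67 to -0.43 over 100). Their covariance was -0.092 against -0.088 simulated (range -0.12 to -0.063), a difference of -0.0039. The simulated spread was taken from the deposited p-values, and for genes at the lowest p-value it grows with the effect. Real effects thus enter the simulations as spread. The likeness of observed and simulated values therefore does not decide how much of the correlation the shared pool gives. The deposited values are pooled per group, so the shared pool could not be split, and part of the excess over independent lists may come from it.

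**Figure D3:**
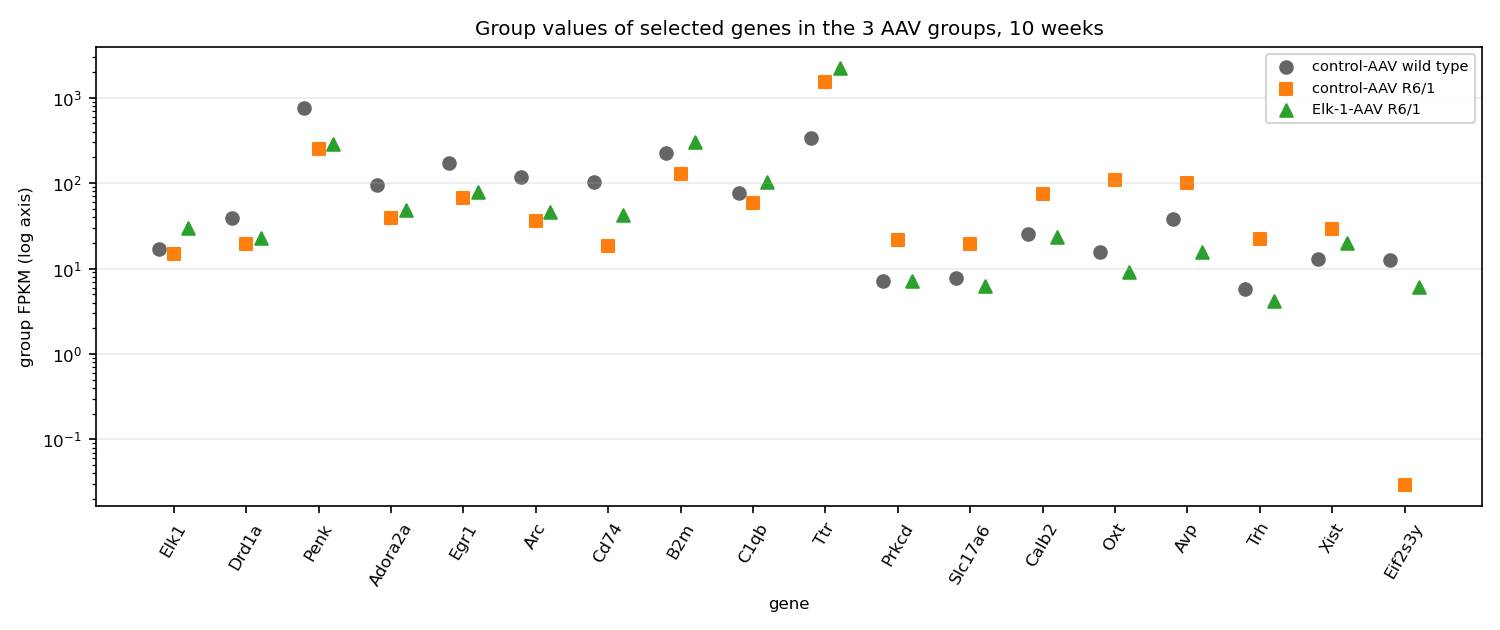
Group FPKM of selected genes (horizontal axis) on a log axis in control-AAV wild type (circles), control-AAV R6/1 (squares) and Elk-1-AAV R6/1 (triangles), from the authors' deposited tables; each symbol is 1 pooled value without an error. Oxt stands at 15.7 in control-AAV wild type, 110 in control-AAV R6/1 and 9.04 in Elk-1-AAV R6/1, whereas Cd74 stands at 103, 18.2 and 41.9.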

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

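All tests in this part were chosen only after the results they bear on had been seen. Intervals of medians in this part are bootstrap intervals over genes and hold no spread between libraries or animals. What is said to argue against a cause therefore holds for these pools only.

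Among the genes named in both comparisons, 2 passed the test, built from the deposited p-values, of a difference in genotype effect between 8 and 4 weeks; it can miss differences of genes at the lowest p-value. Calb2, which encodes calretinin, went from -0.34 to 0.81 in the authors' deposited tables, a difference of 1.15 (adjusted p = 0.00160). The hypothalamic marker Oxt passed the same test in the same direction (adjusted p = 0.00926). A different share of neighbouring tissue between the pools was not tested as a cause. Ugt8a, an enzyme of myelin lipid synthesis, went from 0.17 to -0.46 in the authors' deposited tables, a difference of -0.63 (adjusted p = 0.0341).

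Hypothalamic and thalamic markers were higher in the control-AAV R6/1 pool than in both other AAV pools, and 31 of the 35 genes called lower under Elk-1 AAV were called higher in that pool than in control-AAV wild type. In uninjected mice the septal and hypothalamic list went both ways. Its median was -0.32 (percentile 0; 3 called lower) in R6/1 at 4 weeks and 0.58 (percentile 100; 8 called higher) in CHL2. Thalamus and pallidum genes stood at 0.053 and 0.015 there, inside the random range. Shares of neighbouring tissue in those pools were not tested, so the change of sign does not decide between genotype and tissue. R6/1 genotype as the whole cause is argued against, because the Elk-1-AAV R6/1 pool has that genotype too. Its summed medians over control-AAV wild type were -0.074 for thalamus and pallidum genes and -0.15 for septal and hypothalamic genes. A genotype effect that Elk-1 AAV undoes stays open. In uninjected R6/1 striatum at 8 weeks the 14 thalamus and pallidum markers measured at both ages had a median change of -0.014 (bootstrap 95% interval -0.14 to 0.28, with 7 above 0). The 12 septal and hypothalamic ones had 0.091 (-0.20 to 0.59, with 7 above 0). At 10 weeks these medians were 0.89 and 1.14. However, all 13 septal and hypothalamic genes tested at 8 weeks lay at 0.17 (percentile 99.73). Of the 35 genes lower under Elk-1 AAV, 12 were called higher at 8 weeks against 0.299 expected. Neighbouring tissue carried into the control-AAV R6/1 pool at dissection cannot be told apart from such a genotype effect. In that pool 25 of 28 markers (89.3%) were higher in both comparisons, which restates the pattern and decides nothing. Of other neighbouring tissue, 4 of 18 choroid plexus and ependymal and 1 of 15 cortical excitatory neuron genes were higher there in both. In uninjected wild-type striatum at 8 weeks, 13 of the 17 thalamus and pallidum genes and 11 of the 16 septal and hypothalamic genes had an FPKM of at least 1. The 8-week wild-type pool may itself hold neighbouring tissue, so these counts do not tell striatal expression from carried tissue. Oxt, Avp and Pmch stood at 110, 99.3 and 108 in the control-AAV R6/1 pool in the authors' deposited table. If that pool held less striatal RNA, this may also account for the higher projection neuron values under Elk-1 AAV: the 48 lowered genes of the projection neuron lists had a median of 0.19 (0.16 to 0.23) and the 639 others 0.15, with cortical excitatory neuron genes at 0.20, so the 2 readings cannot be told apart. The pools also differ in sex-linked transcripts, with Y-linked genes near 0 in that pool, and an effect of sex was not tested.

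Interferon and antigen presentation genes were lower in the control-AAV R6/1 pool than in both others. Elk-1 AAV as the whole cause is argued against, because the control-AAV pools, which have no Elk-1 vector, differed by a median of -0.92 (-1.12 to -0.63). R6/1 genotype as present at 8 weeks is argued against by the uninjected mice, where the list was higher by 0.25 (0.15 to 0.35), while it stood at -0.024 in R6/1 at 4 weeks and at -0.17 (percentile 0; 26 of 34 genes below 0) in CHL2, and an effect of genotype that arises by 10 weeks was not tested. A different share of microglia would move the microglial list about as much, but its median between the control-AAV pools was -0.19 (-0.27 to -0.14), which argues against it there; under Elk-1 AAV it was 0.48 (0.40 to 0.61), where such a part stays open. A response to injection or vector dose that differs between pools, leukocytes, and sex stay open and untested, as does a part played by Elk-1 in the rise over control-AAV wild type, whose median was 0.39.

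Genes called higher in R6/1 at 4 weeks have long transcripts. A length trend between the 2 pools is consistent with this: over the genes not called, change and length correlated at 0.48. The 40 genes had a median of 0.39 (0.35 to 0.42) after the trend was taken off, against 0.46 before. They were chosen for their rise, while the median change of the longest decile of genes was only 0.12. Taking off such a median trend had to leave most of their rise, so this does not decide how much of it comes from length. An R6/1 effect lasting to 8 weeks cannot be told apart from none, as the same genes had a median of -0.043 (-0.12 to 0.019) then, with 25 below 0. RNA integrity or library preparation that differs between the pools may give such a trend and was not tested; an effect of genotype present at 4 weeks alone stays open.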

How the results depend on the processing

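The limit on fold size, the matching on and correction for transcript length, and the removal of gene lists, small RNA names and genes sharing a position were chosen after seeing the data. No paired analysis was possible because the deposited columns are pooled per group and carry no replicate numbers. For the same reason leaving out libraries, limma with or without a trend, the estimated correlation, recovered read counts and other splits of the samples were not run. What depth limits is unknown. At q below 0.01 the counts became 0 at 4 weeks, 557 at 8 weeks, 309 in CHL2, 264 in control-AAV mice and 0 under Elk-1 AAV. The counts of 0 follow from the lowest q those tables can hold, 0.0145 and 0.0122. At an unadjusted p below 0.05 they list 780 and 624 genes, against 727 and 635 expected by chance. With a change of at least 1.5-fold, 35 genes remained at 4 weeks, 561 at 8 weeks and 238 in CHL2, by the construction of that limit. All other thresholds and filters kept these counts within 1.5 times. Of the 87 lists outside the random range, 70 stayed so in the same direction under all 6 settings. Of the 87, 10 were lost with matching on transcript length, among them oxidative phosphorylation genes at 4 weeks and receptors in CHL2 (percentile 92.43). With that matching 2 other lists came to lie outside. They were choroid plexus and ependymal genes at 4 weeks (percentile 97.84) and potassium and calcium channels in CHL2 (percentile 0.13). The blood list between control-AAV pools turned from -0.45 to 0.072 with a mean FPKM of at least 2, which leaves fewer genes; the cause was not tested further. The median of the 8-week lowered genes under Elk-1 AAV lay between 0.12 and 0.17 under 9 alternatives and that of the raised genes between -0.34 and -0.20, each outside its random range. At unadjusted p below 0.01 the shared rises at 4 and 8 weeks passed (odds ratio 5.53, against 3.24), and no other same-direction overlap of genotype effects changed its call. Of the other overlaps, genes lower at 8 weeks and higher under Elk-1 AAV passed at that threshold (39 shared against 7.92 expected, adjusted p = 2.99e-17; 3 against 1.85 among called genes). So did those lower at 4 and higher at 8 weeks (7 against 1.71) and those higher in both AAV comparisons (6 against 1.77). Those higher at 8 weeks and under Elk-1 AAV no longer did (adjusted p = 0.162, against 0.00533).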

Other observations

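Of 18 choroid plexus and ependymal genes, 9 fell in R6/1 at 8 weeks (Kl from 16.0 to 7.68 in the authors' deposited table), and 9 of 18 rose in the control-AAV R6/1 pool. Ttr stood at 545 and 660 at 4 weeks and at 1455 and 560 at 8 weeks in the authors' deposited tables. It stood at 1334 and 926 in the CHL2 comparison and 333 and 1547 in control-AAV mice, wild type first, in the authors' deposited tables. Only the last of these 4 differences was called. The imprinted genes Magel2 and Peg10 were called in several tables: Magel2 was lower in R6/1 at 4 weeks and higher at 8 weeks, in CHL2 and in the control-AAV R6/1 pool, and lower under Elk-1 AAV. Ndn, from the same imprinted region as Magel2, had effects of 0.44 in R6/1 at 8 weeks and -0.81 in CHL2 in the authors' deposited tables.

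Cd4, placed on the leukocyte list, fell with the projection neuron genes: from 24.8 to 9.40 in R6/1 at 8 weeks, from 20.2 to 12.7 in CHL2 and from 14.2 to 5.50 in control-AAV mice in the authors' deposited tables. It stood at 5.63 and 6.39 under Elk-1 AAV in the authors' deposited table, without a call, where Ccl5 of the same list stood at 0.956 and 12.6 (q = 0.812). The 56 clustered protocadherin genes had small positive medians of 0.085, 0.087 and 0.094 at 4 weeks, 8 weeks and in CHL2 with 0 genes called. At 8 weeks the list lay inside the random range with a mean FPKM of at least 2 (percentile 93.91). In CHL2 it did so with matching on transcript length (percentile 92.99). Ribosomal protein genes had medians of 0.26 between the control-AAV pools and 0.11 under Elk-1 AAV, with Rps14 called in the latter (108 to 174, q = 0.0215 in the authors' deposited table).

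Other lists gave these medians, in the order 4 weeks, 8 weeks, CHL2, control-AAV genotypes and Elk-1 AAV. Ternary complex factors and SRF cofactors stood at 0.093, -0.20, -0.0068, -0.22 and 0.24, with Srf called lower at 8 weeks and Elk1 higher under Elk-1 AAV. Cholesterol synthesis genes stood at -0.044, -0.25, 0.019, -0.22 and -0.055, interneuron genes at 0.058, -0.31, -0.14, -0.19 and -0.071, and potassium and calcium channels at 0.10, -0.25, -0.023, -0.25 and -0.0020, with 10 channels lower between control-AAV genotypes. In CHL2, 8 of 38 channels were called lower and 3 higher. The channel list lay there at percentile 31.01, or at 0.13 among random lists matched on transcript length too. Oligodendrocyte precursor genes stood at 0.023, -0.088, 0.083, 0.23 and -0.019, endothelial and mural genes at 0.0045, -0.059, -0.15, -0.13 and 0.22, and leukocyte genes at -0.018, 0.097, -0.28, -1.23 and 0.49. Chaperones stood at -0.051, 0.017, 0.071, 0.18 and -0.23, and replication-dependent histones at -0.17, 0.099, -0.056, 0.36 and -0.051.

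In the same order, neurotransmitter receptors stood at 0.074, -0.25, 0.068, -0.27 and -0.084, with 4 called lower between control-AAV genotypes, Cnr1, Chrm4, Gabrd and Chrm1, and 0 called under Elk-1 AAV (percentiles 0 and 0.29). Oligodendrocyte genes stood at 0.012, -0.18, -0.31, 0.18 and 0.037, astrocyte genes at -0.054, -0.060, -0.026, 0.091 and -0.012, with Fabp7 called lower under Elk-1 AAV, and microglial genes at -0.043, -0.035, -0.22, -0.19 and 0.48. Cortical excitatory neuron genes stood at 0.018, -0.50, -0.043, -0.78 and 0.20, with Neurod1 and Bhlhe22 called higher in CHL2, choroid plexus genes at 0.042, -1.01, -0.042, 1.29 and 0.43, and thalamus and pallidum genes at 0.053, 0.017, 0.015, 0.89 and -0.80. Blood genes stood at -0.20 (percentile 0.01), -0.071, -0.85, -0.45 and -0.043, with 0 called at 4 weeks. Direct and indirect pathway genes stood at -0.19 (percentile 1.80) and -0.70 (percentile 0) between control-AAV genotypes. Oxidative phosphorylation genes stood at 0.066 at 8 weeks (percentile 100, with 0 called), -0.0033 between control-AAV genotypes and 0.069 under Elk-1 AAV. Ribosomal protein genes stood at -0.0072 at 8 weeks, and clustered protocadherins at 0.037 and 0.035 in the last 2 comparisons.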
